A study of Caenorhabditis elegans with 4 samples.

How the data were processed

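Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where TAF-1 sits on the genome of mixed-stage Caenorhabditis elegans embryos. The worms were of the N2 strain, the wild-type laboratory reference, and were grown at 20 °C. Per the labels' protocols, embryos were fixed in 2% formaldehyde for 30 min, sonicated, and 2 mg of extract went into each immunoprecipitation, with 10% set aside as input DNA. The antibody is an affinity-purified rabbit polyclonal raised against TAF-1. The series holds 4 libraries, 2 TAF-1 ChIP libraries and 2 input DNA libraries, with the replicate numbers taken from their titles. The labels do not say whether the replicates came from separate cultures, so agreement between them may be technical as well as biological.

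Peak lists were analysed for the 2 ChIP replicates and for the series as a whole. The input libraries have no peak list of their own and were not analysed here. Per the submitters' processing notes, BWA was used with the ce10 build, and its version is not given in the sources used here. Per the file headers, coordinates are on WormBase WS220. The caller is named in the lists themselves, as MACS for each replicate and as MACS v2 for the series list. How the input was used, which cutoffs were set, and whether the series list was called on pooled reads are not given in the sources used here. The only value per peak is the caller's score, as deposited, and the file headers give no scale for it. Replicate scores start at 50.01 and 50.03. They stop at 3100 for 109 replicate 2 peaks and 31 replicate 1 peaks, and 2 replicate 1 peaks lie above that value. Series scores run from 1.3 to 184.55. Scores were therefore used to rank or filter peaks within a list and, between the replicates, for correlations of ranks and of log10 scores, which include the scores at 3100. Replicate and series scores are not on a shared scale. Read depth is unknown, because no list gives a read count. All intervals below are 95% intervals for counting error over peaks, and neighbouring peaks are not independent.

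Chromosome lengths were replaced by spans, running from base 1 to the last peak end in any of the 3 lists. Mitochondrial peaks were left out of all tests. Peaks were called shared when they overlapped by at least 1 bp, and the observed number was compared with 1000 circular shifts of the other list within each chromosome (one-sided). For score comparisons, overlapping peaks were paired one to one in order of shared bases, and Spearman's rho and Pearson's r of log10 scores were tested with 100000 two-sided permutations. Scores of shared and unshared peaks were compared as the probability that a shared peak outranks an unshared one, with the same number of permutations. The density on X was compared with that on the autosomes by a two-sided exact binomial test against the X share of the span. The share of autosomal peaks with their midpoint in the centre of their chromosome, the central 33.3% of its span, was tested against 33.3% in the same way. These 7 main tests were adjusted together by the Benjamini-Hochberg method. Shares carry exact Clopper-Pearson intervals and densities exact Poisson intervals. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The overlap test was tested on the 1882 replicate 1 peaks against simulated replicate 2 lists with randomly placed peaks, using fewer shifts than the analysis. Planted shares of 10%, 30% and 60% were estimated at 10.1%, 31.4% and 62.4%, each in a single simulation, and 7.5% of a small set of unrelated lists passed a threshold of 0.05. A planted X to autosome density ratio of 1.3 in 2984 peaks was estimated at 1.31 on average. Those counts were drawn from the same binomial model as the test, so this checks the calculation and not the effect of clustered peaks.

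These tests, the alternatives and the rule for named peaks were fixed before the data were examined, except where stated. The alternatives were a 50% reciprocal overlap, midpoints within 100 bp, the top 50% of a list by score, lists of equal size, random placement, peak width in place of the score, each replicate list in place of the series list, and series peaks found in both replicates. The named peaks are the 10 with the highest series scores and the highest-scoring peak of each chromosome. Planned comparisons with annotated gene starts, fixed gene lists and gene counts were not made. The gene table at hand is on WBcel235, a different build from the peaks, so no peak was assigned to a gene.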

Results

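TAF-1 occupancy was profiled by ChIP-seq in mixed-stage wild-type C. elegans embryos. TAF-1 is the largest subunit of TFIID, the general transcription factor that recognises core promoters and helps to position RNA polymerase II. The series list held 2987 peaks, of which 2984 lay on the 6 nuclear chromosomes and 3 on mitochondrial DNA. Replicate 1 had 1883 peaks, 1 of them mitochondrial, and replicate 2 had 2090, all nuclear. Series peaks were narrow, with a median width of 241 bp (quartiles 183 and 344 bp). Replicate 1 peaks had a median width of 430 bp (quartiles 316 and 612 bp) and replicate 2 peaks of 1145 bp (quartiles 999 and 1604 bp). The peaks covered 0.952 Mb in the series list, 1.11 Mb in replicate 1 and 3.00 Mb in replicate 2.

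The strongest TAF-1 sites were spread over all 6 nuclear chromosomes, and all 10 of the highest-scoring series peaks overlapped a peak in each replicate. Chromosome I held 3 of them, chromosomes II and V held 2 each, and III, IV and X held 1 each. The highest series score, 184.55, was shared by a 496-bp peak on chromosome II (11545165 to 11545660, WS220) and a 522-bp peak on chromosome IV (15561193 to 15561714). The replicate 1 peaks at these sites scored 2369.54 (rank 50) and 1782.38 (rank 77). The next peak lay on chromosome I (5379659 to 5380213) and scored 184.48. Chromosome V followed with a 1231-bp peak at 9089251 to 9090481, which scored 182.08, and a 654-bp peak at 1804808 to 1805461, which scored 181.83. The strongest peak of chromosome III (9053574 to 9054219) scored 157.22, and the strongest of X (11937189 to 11937700) scored 156.85. The remaining members of the top 10 were at 9631680 to 9633152 on chromosome II (160.46), at 4573057 to 4573871 on chromosome I (158.41) and at 14686320 to 14687413 on chromosome I (153.44). In replicate 2, the overlapping peak reached the score ceiling of 3100 at all 10 sites. In replicate 1, the overlapping peak scored 3100 or more at 3 of them. Whether these sites are promoters, exons or introns was not analysed here, since no gene annotation on WS220 was used.

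The comparison of the ChIP replicates asked whether both found TAF-1 at the same places. Most replicate 1 peaks, 1272 of 1882 (67.6%, 95% interval 65.4 to 69.7%), overlapped a replicate 2 peak. In the other direction, 1131 of 2090 replicate 2 peaks (54.1%, 52.0 to 56.3%) overlapped a replicate 1 peak. Circular shifts of the other list gave 4.25% and 3.62% on average, so the observed shares were 15.9 and 14.9 times those of shifted lists. The 1000 shifts gave at most 171 and 130 shared peaks. The permutation p of 0.001 in both directions was the smallest the shifts can give (one-sided, adjusted p = 0.0012). When each pair of peaks had to cover at least 50% of each other, 14.9% of replicate 1 peaks and 13.4% of replicate 2 peaks were shared. Under that rule the wide replicate 2 peaks cannot match narrow replicate 1 peaks. With midpoints within 100 bp, 38.3% of replicate 1 peaks were shared.

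Strong sites were shared far more often than weak ones. In replicate 1, the top 25% of peaks by score was shared at 91.7% (432 of 471) and the bottom 25% at 45.2% (213 of 471). In replicate 2, the top 25% was shared at 94.8% (496 of 523) and the bottom 25% at 25.6%. A shared peak outranked an unshared peak with a probability of 0.742 in replicate 1 and 0.812 in replicate 2. The median score was 177 for shared and 84.8 for unshared replicate 1 peaks, and 289 and 86.03 in replicate 2. Both permutation p-values were 1e-05, the smallest that 100000 permutations can give (two-sided, adjusted p = 1.7e-05). Shared peaks were also wider, with median widths of 488 bp against 326 bp for unshared peaks in replicate 1 (probability 0.735) and 1211 bp against 1079 bp in replicate 2 (0.628), and a wide peak has more chance to overlap another.

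Scores of the same site ranked alike in the 2 replicates. Over 1131 one-to-one pairs, Spearman's rho was 0.744 and Pearson's r of log10 scores was 0.802, each with a permutation p of 1e-05, the smallest possible (two-sided, adjusted p = 1.7e-05 for rho). These are correlations across peaks, which are not independent replicates. Without the pairs that touched the ceiling of 3100, 1022 pairs remained and rho was 0.661, in a comparison chosen after seeing the data.

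**Figure D1:**
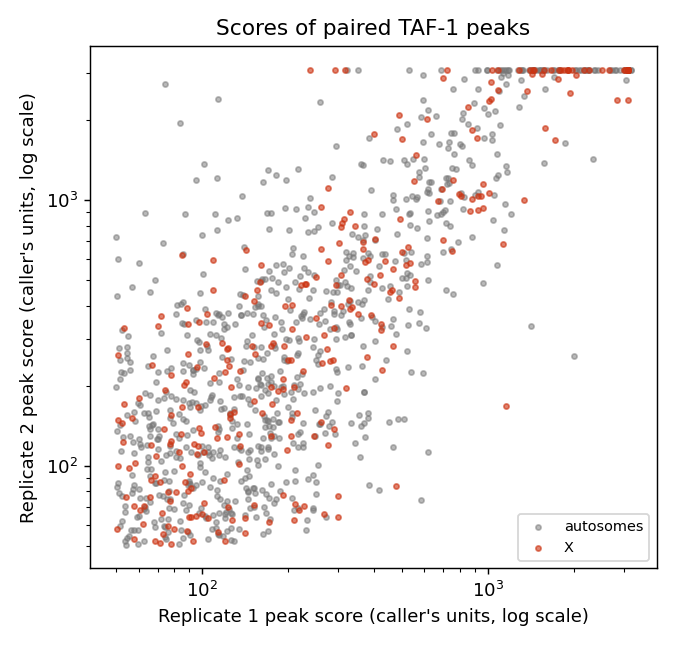
Each point is 1 of 1131 one-to-one pairs of overlapping peaks, with the caller's score in replicate 1 on the x axis and in replicate 2 on the y axis, both log scales, and X-linked pairs in red. Scores rise together (Spearman's rho 0.744), and many replicate 2 peaks sit at the ceiling of 3100.

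The series list was then set against the replicates to see how much of it each one held. Of the 2984 nuclear series peaks, 1247 (41.8%, 40.01 to 43.6%) overlapped a peak in both replicates. Another 503 (16.9%) overlapped replicate 1 only, 369 (12.4%) replicate 2 only, and 865 (29.0%, 27.4 to 30.7%) neither. The series list shifted against both replicate lists together, which keeps the overlap of the replicates, gave 1.21% in both on average and 8.04% at most, in a comparison chosen after seeing the data. Replicate lists shifted separately gave 1.71% in replicate 1, 3.78% in replicate 2 and 0.0694% in both. Series peaks found in both replicates had a median score of 18.1 (quartiles 8.40 and 37.9). The medians were 9.95 for replicate 1 only, 5.64 for replicate 2 only and 5.35 for neither. No series peak above a score of 18.76 was missing from both replicates. Among the top 50% of the series list by score, 62.2% of peaks were found in both replicates. With a reciprocal overlap of at least 50%, 2.75% were.

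**Figure D2:**
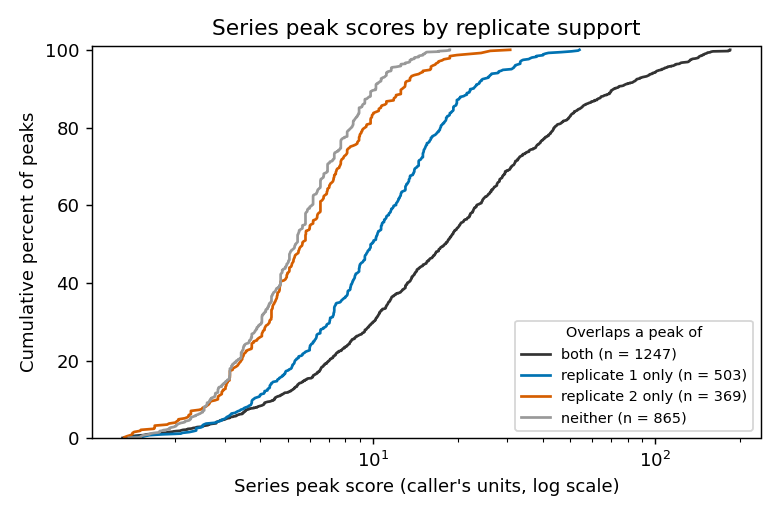
Cumulative percent of series peaks (y axis) against series peak score in the caller's units (x axis, log scale), for peaks that overlap a peak of both replicates, of 1 replicate only or of neither. The curve for both lies farthest right, with a median score of 18.1 against 5.35 for neither.

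TAF-1 peaks were denser on the X chromosome than on the 5 autosomes combined. X held 641 series peaks, or 36.2 per Mb (33.5 to 39.2), against 28.4 per Mb (27.3 to 29.6) on the autosomes. X therefore had 21.5% of nuclear peaks on 17.7% of the span, a density ratio of 1.28 (1.17 to 1.39, two-sided exact binomial p = 9.5e-08, adjusted p = 6.7e-07). The ratio was 1.336 (1.195 to 1.49) in replicate 1 and 1.338 (1.205 to 1.48) in replicate 2, and X was the densest chromosome in all 3 lists. Among series peaks found in both replicates, X had 304 of 1247 peaks (24.4%), a ratio of 1.50 (1.32 to 1.71). Among the other 1737 series peaks the ratio was 1.12 (0.99 to 1.27), and the X share differed between these classes (Fisher's exact p = 0.0011, odds ratio 1.34, chosen after seeing the data). X is a single chromosome, so an exact permutation test that treats whole chromosomes as the units cannot go below p = 0.167.

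The autosomes differed among themselves. Comparisons of X with single autosomes were not among the planned tests. Chromosome V was the sparsest in every list, with 21.3 series peaks per Mb (19.4 to 23.4), and the X to V ratio was 1.70 (1.50 to 1.92, exact binomial adjusted p = 6.7e-17 over 15 comparisons). Chromosome III had 35.7 series peaks per Mb (32.6 to 39.0), and the X to III ratio of 1.02 (0.90 to 1.14, exact binomial adjusted p = 0.81) did not differ from 1. Nor did the X to I ratio of 1.10 (0.98 to 1.24, exact binomial adjusted p = 0.12). Among series peaks found in both replicates, however, X exceeded I by a ratio of 1.42 (1.18 to 1.72, exact binomial p = 0.00015) and III by 1.33 (1.10 to 1.61, exact binomial p = 0.0024), values not adjusted and chosen after seeing the data. In the whole series list, ratios to chromosomes II and IV were 1.31 and 1.296 (exact binomial adjusted p = 4.6e-05 and 4.7e-05). In replicate 2, X exceeded chromosome III by a ratio of 1.24 (1.06 to 1.43, exact binomial adjusted p = 0.0073). In replicate 1 that ratio was 1.17 (1.00 to 1.37, exact binomial adjusted p = 0.059). The X to I ratio was 1.14 (0.99 to 1.33, exact binomial adjusted p = 0.094) in replicate 1. It was 1.12 (0.97 to 1.29, exact binomial adjusted p = 0.12) in replicate 2.

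**Figure D3:**
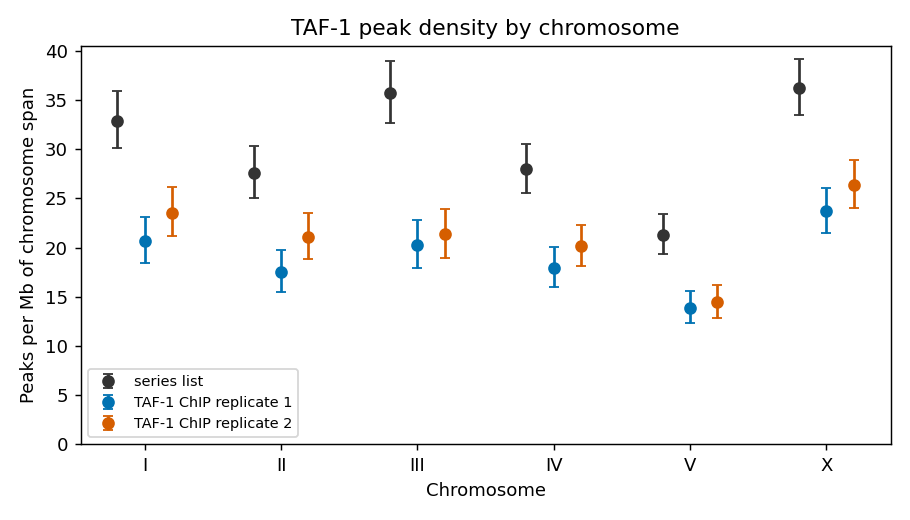
Peaks per Mb of chromosome span (y axis) on each nuclear chromosome (x axis) in the series list and the 2 replicates, with exact 95% Poisson intervals as bars. X is the highest and V the lowest in each list, while III is close to X in the series list.

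Along the autosomes, the share of series peaks in the chromosome centres did not differ from an even spread, and the centres held a smaller share of replicate 2 than of replicate 1 peaks. Autosome centres of C. elegans are known for conserved, widely expressed genes, and the flanking arms for repeats and fast-evolving gene families. The centre, taken as the central 33.3% of each span, held 790 of 2343 autosomal series peaks (33.7%, 31.8 to 35.7%), which did not differ from 33.3% (two-sided exact binomial p = 0.69, adjusted p = 0.69). In replicate 1 the share was 36.7% (34.2 to 39.2%, exact p = 0.0066) and in replicate 2 it was 28.7% (26.5 to 30.96%, exact p = 6.3e-05). The replicates differed by 8.01 percentage points (4.70 to 11.3, Fisher's exact p = 2.2e-06, a comparison chosen after seeing the data). Fisher's test counts neighbouring and shared peaks as independent, and this difference was not tested by circular shifts. Circular shifts, which keep the spacing of neighbouring peaks and were also chosen after seeing the data, gave permutation p = 0.09 for replicate 1 and p = 0.043 for replicate 2, so that by this test replicate 1 was not distinguished from an even spread.

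Shared peaks mark the same sites in both lists, so by construction the difference had to come from the peaks that only 1 replicate had. Shared peaks lay in the centre at 37.5% by replicate 1 positions and at 37.96% by replicate 2 positions. Among unshared autosomal peaks, 173 of 492 replicate 1 peaks (35.2%) but only 143 of 773 replicate 2 peaks (18.5%, 15.8 to 21.4%) lay there, a difference of 16.7 points (11.6 to 21.7, Fisher's exact p = 4.9e-11, also chosen after seeing the data). Circular shifts gave permutation p = 0.004 for the unshared replicate 2 share and 0.44 for that of replicate 1, and did not test the difference. Series peaks supported by replicate 2 only, not a set independent of that list, were in the centre at 19.6% (15.3 to 24.5%). Those supported by both replicates were there at 38.4% (35.3 to 41.6%, exact binomial p = 0.0012 against 33.3%), a share that circular shifts did not distinguish from an even spread (permutation p = 0.062).

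**Figure D4:**
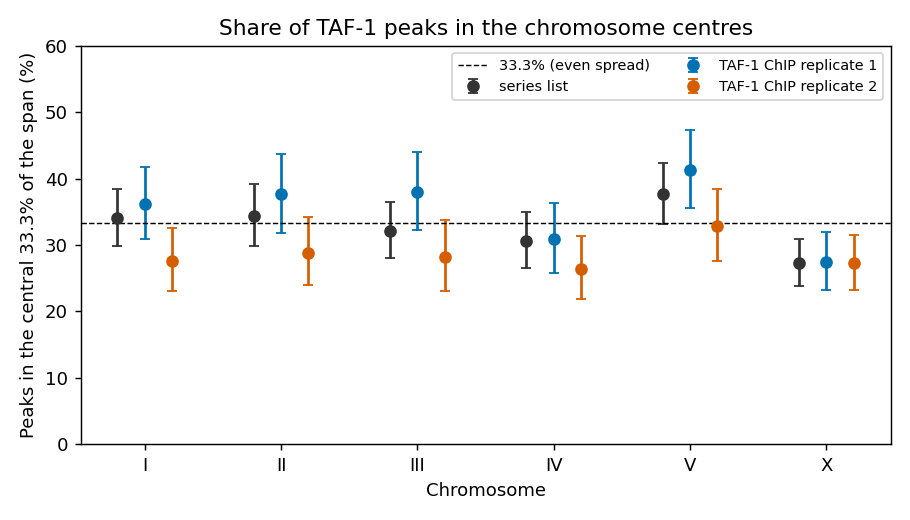
Percent of peaks with their midpoint in the central 33.3% of the chromosome span (y axis) for each nuclear chromosome (x axis) and list, with exact 95% binomial intervals and a dashed line at 33.3%. Replicate 1 lies above replicate 2 on all 5 autosomes, and all lists are near 27% on X.

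**Figure D5:**
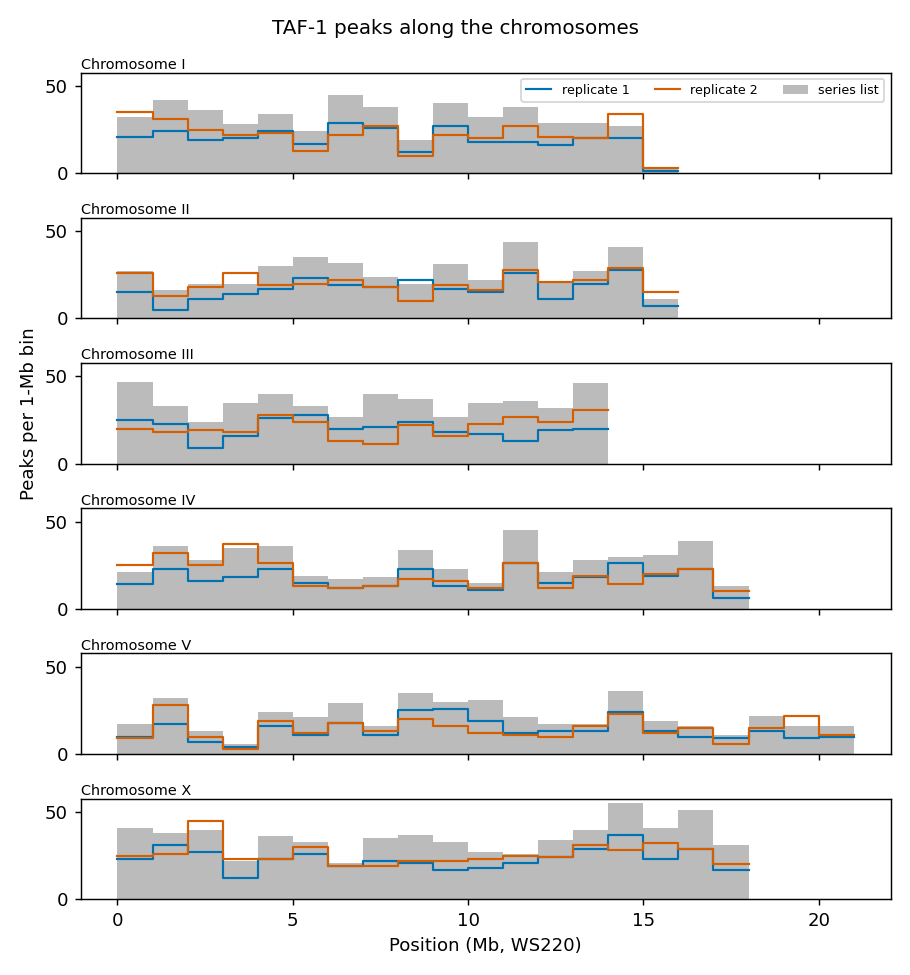
Number of peak midpoints per 1-Mb bin (y axis) along each nuclear chromosome (x axis, Mb, WS220) for the series list (grey bars), replicate 1 (blue line) and replicate 2 (orange line). Peaks occur along the whole length of every chromosome, and chromosome V is the sparsest.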

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

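The density ratio of X to the autosomes kept its direction and stayed past the threshold in 5 of 6 alternatives, of which peaks within 10 kb counted once (1.25) was chosen after seeing the data. It lay between 1.336 and 1.338 when either replicate list replaced the series list, and was 1.50 for series peaks found in both replicates. Against chromosome III alone, an alternative chosen after seeing the data, it was 1.02 and no longer past the threshold, since III was almost as dense as X. Among peaks found in both replicates the X to III ratio was 1.33 (1.10 to 1.61). The ratio to chromosome I alone, not counted among these alternatives, was 1.10 (0.98 to 1.24, exact binomial adjusted p = 0.12), and 1.42 among peaks found in both replicates. The share of autosomal peaks in the chromosome centres depended on the list. It ranged from 28.7% to 36.7% over the lists of single replicates, the lower value from replicate 2 alone being on the other side of 33.3%. It passed the threshold at 36.1% in the top 50% by score (exact p = 0.045) and at 38.4% among peaks found in both replicates by the exact binomial test, but not by circular shifts chosen after seeing the data (permutation p = 0.21 and 0.062), and the cause of these shifts was not tested. The share of series peaks found in both replicates moved from 41.8% to 62.2% in the top 50% by score and to 2.75% with a 50% reciprocal overlap, where differences in width limit what can match. Replicate overlap, the correlation of scores and the scores of shared against unshared peaks stayed past the threshold in all alternatives run, with rho between 0.661 and 0.861. Overlap with a replicate left out has no value. Alternatives that need annotated gene starts, gene lists or gene counts were not run. No paired analysis was possible because the input libraries, which share the replicate numbers of the ChIP libraries, have no peak list here. Depth is unknown, so a peak missing from a list does not show that TAF-1 is absent there.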

Other observations

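Of the tests in this part, the X ratio in the top 50% of series peaks was planned before the data were examined, and the others were chosen after seeing the data. TAF-1 peaks lay closer together than random placement would put them. In the series list, 13.9% of neighbouring peaks were within 1 kb of each other, against 3.95% on average and 4.67% at most in 200 random placements. Replicate 1 gave 11.1% against 3.01%, and replicate 2, with its wide peaks, 7.58% against 5.07%. A few regions were covered in one continuous stretch, named here after their values were seen. The widest series peak spanned 8278 bp on chromosome V (7916804 to 7925081, score 148.53). The next widest scored far lower, 12.77 for a 4783-bp peak on chromosome III, and 6.95 and 7.3 for peaks of 4289 and 4267 bp on X. A 3487-bp peak on chromosome II (11757821 to 11761307) scored 149.35. The densest 100-kb window, on X from 7300001 to 7400000, held 14 series peaks. In 200 random placements the densest window held a median of 10 peaks and at most 14. The mitochondrial peaks were at 4573 to 4767, 4906 to 5064 and 12261 to 12617 in the series list, with scores of 9.47, 2.41 and 1.76. Replicate 1 had a single 2666-bp mitochondrial peak at 10702 to 13367, with a score of 535.03.

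Of the 1272 replicate 1 peaks shared with replicate 2, 83 (6.53%) had no series peak. These had a median replicate 1 score of 80.9 against 190 for the others, and 7 lay within 20 kb of a chromosome end, against 3 of the others. The highest-scoring one spanned 4231 bp on X (15807055 to 15811285, replicate 1 score 2829.13). On every nuclear chromosome a further one started at base 1, with replicate 1 widths from 211 bp (IV) to 526 bp (I). Their replicate 2 partners started at base 1 or 2. Over 1063 series peaks with a partner in both replicates, series scores followed replicate 1 more closely (Spearman's rho 0.745) than replicate 2 (0.545, difference 0.201, bootstrap interval 0.167 to 0.237). The ceiling is unequal, with 107 of these sites at 3100 or more in replicate 2 and 28 in replicate 1, and over the 955 sites below it in both the values were 0.700 and 0.435 (difference 0.266, 0.222 to 0.312). The pairing is unequal too. Of 1750 series peaks that overlapped replicate 1, 1660 had a one-to-one partner, against 1344 of 1616 for the wider replicate 2 peaks. Whether this lowered rho for replicate 2 was not tested. On X, the central 33.3% of the span held 27.3% of series peaks, 27.4% of replicate 1 peaks and 27.3% of replicate 2 peaks. Exact binomial tests gave adjusted p = 0.019, 0.040 and 0.025 over 18 comparisons, and circular shifts gave permutation p = 0.20, 0.098 and 0.039. The same exact tests also called replicate 2 on chromosome IV (26.4% in the centre, adjusted p = 0.025) and, in the opposite direction, replicate 1 on V (41.4%, adjusted p = 0.025).

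The first pattern is the excess of peaks on X. More closely spaced calls on X do not account for it, since the ratio was 1.25 (1.12 to 1.40) with peaks within 10 kb counted once. Nor do weak calls on X, since the top 50% of series peaks by score gave 1.25 (1.10 to 1.41). What stays open is a difference in gene density or gene content between chromosomes, mappability, the input level on X, and a biological preference. The design has no second group of embryos, so no biological explanation was tested.

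The second pattern is the excess of unshared replicate 2 peaks in the outer parts of the autosomes, outside the central 33.3%, with 18.5% of them in the centre (permutation p = 0.004 by circular shifts). Close calls split or merged differently do not account for the whole difference between replicates, which was 8.01 points over all peaks and 6.31 points (2.39 to 10.2) with peaks within 10 kb counted once. The first test of weak calls, on the top 50% of all replicate 2 peaks by score, left them undecided, with 32.4% (29.2 to 35.7%) in the centre, although the replicates still differed there by 5.22 points (0.45 to 9.99, Fisher's exact p = 0.032, with peaks counted as independent). That set is mostly shared peaks, so after this result the test was replaced by one on its 192 unshared peaks, of which 14.6% (9.91 to 20.4%, permutation p = 0.014 by circular shifts) lay in the centre, which argues against weak calls. The other 581 unshared autosomal replicate 2 peaks, which scored lower, lay there at 19.8% (16.6 to 23.3%). The deficit was therefore not confined to weak calls. What stays open is a hypothesis that background in repeat-rich arms may differ between the libraries. A real difference between the embryos of the replicates also stays open, if these were separate collections, which the labels do not say. Neither was tested.

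The third pattern is the width of replicate 2 peaks, which were wider than their replicate 1 partners in all 1131 pairs, by a median of 690 bp (quartiles 571 and 1086.5 bp). The narrowest replicate 2 peak, at 672 bp, exceeded the upper quartile of replicate 1 widths (612 bp). Most replicate 1 peaks could therefore only have a wider partner, so this floor largely set the direction. Merging of neighbouring replicate 1 peaks is too rare to account for it, as 9.64% (7.98 to 11.5%) of shared replicate 2 peaks held 2 or more. That count cannot see merging with sites that replicate 1 did not call. A fixed widening of every call passed its first test, a slope of 1 of replicate 2 width on replicate 1 width (0.977, 0.916 to 1.03), but the spread of the differences led to a second test after that result, in which the difference had a Spearman's rho of -0.0563 (-0.118 to 0.0055) with the replicate 1 score, and this left it undecided. Over the 1022 pairs whose replicate 2 peak held 1 replicate 1 peak, the slope was 0.867 (0.808 to 0.924) and rho -0.110 (-0.175 to -0.0475), which goes against it, although noise in replicate 1 widths would also lower the slope. What stays open is merging with sites that replicate 1 did not call, and a fixed widening with noise in the peak edges. Also open are longer fragments or another setting of the peak calling in replicate 2, and a biological difference. None of these was tested further.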
